A study of Mus musculus with 6 samples.

How the data were processed

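RNA of the uterus of pregnant mice was hybridised to 6 Illumina bead arrays, all on 1 chip, labelled with Cy3 per the labels' protocols. The titles put 3 arrays at day 15.5 and 3 at day 18.5 after mating, numbered 1 to 3 within each day. Uterine tissue was lysed in a phenol-based reagent and RNA purified on columns per the labels' protocols, whereas the design text speaks of myometrium. That text also mentions 18 biological replicates per day and 36 samples for expression and microRNA arrays; the labels do not say how many animals stand behind each array, so p-values measure the spread between these arrays, which may be technical in part. Arrays of day 15.5 and day 18.5 took separate stretches of the chip, and no fit can separate day from position.

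The deposited unnormalized table gives, per the file headers, a mean bead signal (intensity) and a detection p-value for each of 45281 probes and array. Its intensities are neither background-subtracted nor normalized, as their differing medians show. The authors' normalized intensity table holds sorted values that differ between arrays by at most 3.89 intensity units, as quantile normalization gives, on a linear scale and background-corrected; the method of background correction is not given in the sources used here. The authors' deposited comparison table repeats these intensities and adds, per the file headers, a ratio of day 18.5 over day 15.5 and a false discovery rate (a q-value). Gene names, ratios and rates in it are sorted apart from the probes of the same line: gene symbol and name in the block matched on 1 line only. Ratios were therefore joined to probes by symbol and by equality with the ratio of the normalized intensities within a relative tolerance of 1e-05, which placed 43887 of 43887 ratios on exactly 1 probe; 1394 lines held no ratio. No column of values lacked a sample.

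Probes were named through RefSeq names of assembly GRCm38.p6, 26889 by accession, 5446 by current symbol and 3934 by synonym; 9012 kept the name in the file, giving 28922 distinct names. Intensities were background-corrected, offset by 16, quantile-normalized and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3), the background being inferred from detection p-values. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, 20701 in all, and each gene was represented by its brightest kept probe, leaving 14081 genes. Of these, 4543 had several kept probes, and 8 called genes had a probe called in the other direction. Days were compared with lmFit and eBayes, without a block, at a two-sided Benjamini-Hochberg adjusted p under 0.05. A gene detected on no array of a day has only a bound there: its fold is given as at least the brighter day's mean over the dimmer day's mean of, per array, the lowest signal among detected probes or the probe's own signal, whichever was higher. There were 175 such genes among those called higher and 146 among those called lower. Each bound holds for this background correction and offset only, and some alternatives below gave smaller folds.

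Of 30 lists of genes, the 29 with at least 5 measured members were tested with camera at its preset correlation of 0.01 and adjustment over the lists. They cover contraction-associated genes, smooth muscle, ion channels, progesterone-related and oestrogen-responsive genes, steroid and prostaglandin metabolism, published miR-200 targets, cytokines, interferon-stimulated and immediate early genes, matrix structure and degradation, cell cycle, oxidative phosphorylation, hypoxia and glycolysis, the unfolded protein response, cholesterol biosynthesis, ribosomal proteins, and markers of epithelium, macrophages, neutrophils, lymphocytes and NK cells, endothelium, decidua, trophoblast, red cells, Y-linked genes, adipose and mesothelium, skeletal muscle, and fibroblasts and pericytes. A member was found by its symbol or by an alternative symbol fixed beside it. With an estimated correlation no list passed. The genes named are 12 genes of the study; the 10 largest rises and 10 largest falls among called genes whose days do not overlap, leaving out 563 called genes without an assigned symbol; up to 4 members of each list, by smallest adjusted p, some of which are not reported here; and the brightest member of each cell type list. Other genes are named where a count of 5 or fewer or a direction called for it, and were chosen after their values were seen. The lists, the naming rule, the test and most alternatives were fixed before the data were examined. Seed matches of miR-200 in transcripts were not searched here, since no transcript sequences were used.

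Alternatives were no background correction, normexp with an offset of 50, neqc with an offset of 50, median scaling, the authors' deposited values, no detection filter, a detection p under 0.01 on all 6 arrays, the mean of a gene's probes, single probes, a trended and robust variance, array weights, the replicate number as a block, an unmoderated statistic, a 2-fold minimum, camera with an estimated correlation, fry, and leaving out each array. On simulated arrays with 200 genes of known change, run for day 18.5 against day 15.5 over 13882 genes, 6.12% of changes of 0.5 (log2), 64.4% of changes of 1, 97.8% of changes of 2 and 100% of changes of 3 were recovered, and 14 of 13696 unchanged genes were called, 10.2% of all calls. With only 200 changed genes the adjusted threshold was stricter than in the data, so these rates do not carry over. A list shifted by 0.5 was called (adjusted p = 3.1e-54), as was 1 of 28 unshifted lists, which shares members with it. Genes were simulated independently of each other, so this does not test list calls where genes are correlated. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots drawn with matplotlib 3.10.9.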

Results

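RNA from the uterus of pregnant mice was measured on 6 Illumina bead arrays of 1 colour, 3 from day 15.5 and 3 from day 18.5 after mating, the later day lying close to term. The sample labels name the tissue as uterus and the design text speaks of myometrium, the muscle layer, so which layers each sample held is not settled. The series title names the miR-200 family, the transcriptional repressors ZEB1 and ZEB2, and the quiescence and contractility of the uterus in pregnancy and labour. The comparison of the 2 days therefore asks how uterine gene expression differs between the quiescent uterus and the uterus shortly before labour. The microRNA arrays of the study were not analysed here. Between 43.6% and 46.5% of the probes were detected on each array, and the median unnormalized signal ran from 75.8 to 105. The 3 arrays per day set the limit of precision, and each day filled its own stretch of a single chip, so day and position on the chip cannot be told apart.

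Gene expression differed widely between the 2 days. Of 14081 genes tested with limma, 1781 were higher and 1888 lower at day 18.5 after Benjamini-Hochberg adjustment, and 555 of the former and 535 of the latter changed by at least 2-fold. The 3 values of each day did not overlap for 43.2% of all genes tested, against 10% by chance. Correlations between arrays of the same day lay between 0.989 and 0.993, and those between days from 0.946 to 0.961. The largest rises belonged to hormones and secreted proteins. Prl7b1, a placental relative of prolactin, was at least 95.4-fold higher at day 18.5 (adjusted p = 5.15e-06), where the bound sets the later mean against the lowest signal of a detected probe, because the gene was detected on no array of day 15.5. The same held for Ceacam11 (at least 40.1-fold), Prl2a1 (at least 31.8-fold), the apolipoprotein gene Apoa1, also a product of the yolk sac (at least 29.3-fold) and Prl2c1 (at least 24.0-fold). These bounds hold for the first fit only. Over the alternatives the log2 change was 5.25 to 7.48 for Prl7b1, 4.27 to 6.99 for Ceacam11 and 4.19 to 7.36 for Prl2a1. It was 3.79 to 6.31 for Apoa1 and 3.44 to 5.84 for Prl2c1. Genes detected on only some arrays of a day also have folds that hang on the treatment of background. Prl2c3 and Prl2c2, detected on 1 and 2 of the day 15.5 arrays, rose by 6.18 (4.68 to 7.02 over the alternatives) and 6.16 (4.73 to 6.94) on the log2 scale. The Prl2c genes are near-identical copies, so each of these probes can also read the others' transcripts. Wfdc12 and Wfdc18, which encode small secreted proteins of the whey acidic protein family, rose by 5.51 and 4.84 on the log2 scale; Wfdc12 was detected on 1 array of day 15.5 (4.01 to 6.37 over the alternatives). Sct, the gene of the peptide hormone secretin, rose 39.6-fold (log2 change 5.31 ± 0.23, SE).

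The 10 largest falls included an ion channel subunit, a water channel and several proteins of cytotoxic cells. Kcne2, a potassium channel subunit detected on 2 of the day 18.5 arrays, fell 32.3-fold (log2 change -5.01 ± 0.31, SE; -5.56 to -3.82 over the alternatives; adjusted p = 1.22e-05). Granzymes, proteases of cytotoxic granules, followed: Gzme fell 23.5-fold, Gzmg 16.4-fold and Gzmf, detected on 2 of the day 18.5 arrays, 16.2-fold (log2 change -4.02; -4.60 to -2.88 over the alternatives). Aqp8, a water channel, fell 17.3-fold, and Ctsg, a leukocyte protease, 12.3-fold. Nptx1 and Tmsb15a, detected on no array of day 18.5, were at least 11.8-fold and at least 7.38-fold lower. Their log2 changes ran from -5.36 to -2.67 and from -4.87 to -2.16 over the alternatives. Sh2d2a, an adaptor of T and NK cells detected on 1 array of day 18.5, fell by 3.53 on the log2 scale (-4.45 to -2.18 over the alternatives). Fam13a fell 11.5-fold (log2 change -3.88 to -2.63 over the alternatives).

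Among the genes of the study, Oxtr and Gja1, which serve contraction, rose, while Zeb1 and Zeb2 fell. Oxtr, the oxytocin receptor, was detected on no array of day 15.5 and on all 3 of day 18.5, where it was at least 4.33-fold higher (adjusted p = 5.15e-06). Its log2 change ran from 1.44 to 3.64 over the alternatives. A further Oxtr probe was detected on no array. Gja1, which encodes the gap junction protein connexin 43, rose from a mean log2 signal of 13.33 ± 0.13 (SD, n = 3) to 14.83 ± 0.10, a 2.83-fold rise (adjusted p = 4.06e-05). Zeb1 fell 1.66-fold, from 10.62 ± 0.21 (SD, n = 3) to 9.89 ± 0.05 (adjusted p = 0.00334), and its other probe fell as well. Zeb2 fell 1.48-fold, from 9.80 ± 0.14 (SD, n = 3) to 9.23 ± 0.14 (adjusted p = 0.0113). The Zeb2 call was lost without the day 18.5 array of replicate 2 (log2 change -0.50, adjusted p = 0.0528; 0.00363 to 0.0528 over the alternatives), and its other detected probe changed by -0.19 (probe-level adjusted p = 0.333). Cdh1, the gene of E-cadherin, which ZEB1 and ZEB2 are known to repress, rose 1.95-fold (adjusted p = 0.00109).

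Of the hormone receptor genes, Esr1 rose and Pgr did not pass the test, nor did the gene of the main progesterone-degrading enzyme. Esr1, the oestrogen receptor gene, rose 1.45-fold (adjusted p = 0.00819), a call lost when all its probes were averaged (log2 change 0.38, adjusted p = 0.0603; 0.00155 to 0.0603 over the alternatives). Pgr, the progesterone receptor gene, changed by 0.24 ± 0.14 (log2, SE; adjusted p = 0.243). Akr1c18, which encodes the 20-alpha-hydroxysteroid dehydrogenase that inactivates progesterone, was at 14.26 ± 0.18 (SD, n = 3) and 14.17 ± 0.12 (adjusted p = 0.668). Acta2, smooth muscle actin, changed by 0.07 at its brightest probe (adjusted p = 0.712), but 3 of its 5 detected probes fell, and the mean of its probes fell by 0.40 on the log2 scale (adjusted p = 0.0214; 0.0214 to 0.995 over the alternatives). Ptgs2, Ptgfr and Stat5b were detected on no array; an undetected probe does not show that a gene was silent, as the undetected second probe of Oxtr makes plain.

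**Figure D1:**
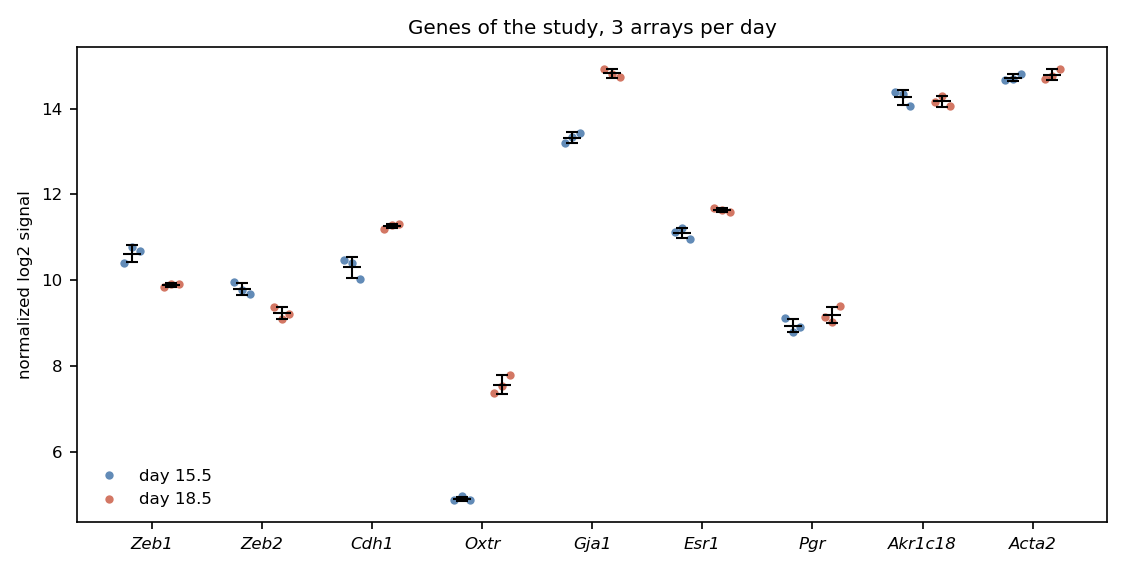
Normalized log2 signal of 9 genes of the study on each of the 3 arrays per day (points, day 15.5 in blue and day 18.5 in red), with the mean and SD of each day (bars); signals are comparable within a gene, not between genes. Oxtr, Gja1, Cdh1 and Esr1 lie higher and Zeb1 and Zeb2 lower at day 18.5; Oxtr at day 15.5 was not detected, and Acta2 is shown at its brightest probe only.

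The wider list of contraction-associated genes did not shift as a whole, because its members went both ways. Oxtr, Gja1, the endothelin receptor Ednra (log2 change 1.24 ± 0.12, SE) and the chemokine Cx3cl1 rose, while the other endothelin receptor, Ednrb, fell by 1.16, the adrenergic receptor Adra2a by 1.15 and the cyclooxygenase Ptgs1 by 0.83. That made 4 of 12 measured members higher, 3 lower and 5 not past the test, or 4 and 6 adjusted over the list alone. The median was -0.27, the mean 0.15, and the camera test of the list gave an adjusted p of 0.998. Of 25 smooth muscle contractile genes, 8 fell, 1 rose and 16 did not pass, with 10 lower and 1 higher adjusted over the list alone. Myocd, the coactivator of smooth muscle gene transcription, fell 5.22-fold (log2 change -2.38 ± 0.11, SE, and -2.43 to -1.78 over the alternatives). The filament gene Synm fell 2.82-fold, whereas Pdlim7 rose. Casq2, a calcium store protein detected on 1 array of day 18.5, fell by 1.76 on the log2 scale (-2.33 to -0.89 over the alternatives). This list lay lower at day 18.5 (median -0.28, adjusted p = 0.00274), which ended with median scaling (median -0.08, adjusted p = 0.116; 0.000107 to 0.116 over the alternatives); the adjusted p was 0.337 with an estimated correlation.

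Among 26 genes of ion channels and calcium handling, 10 fell, 2 rose and 14 did not pass, with 10 lower and 3 higher adjusted over the list alone, and the list as a whole gave a median of -0.22 and an adjusted p of 0.0855. Kcnd2, a voltage-gated potassium channel, was at least 2.90-fold lower and undetected at day 18.5 (log2 change -3.47 to -1.19 over the alternatives). The calcium-activated chloride channel Ano1 and the potassium channel Kcnh2 fell by 0.88 and 0.89 on the log2 scale, and the stretch-activated potassium channel Kcnk2 rose 3.59-fold.

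Targets of steroid hormone signalling changed in both directions. Tsc22d3 and Zbtb16, which glucocorticoid and progestin signalling are known to induce, fell 3.03-fold and 4.52-fold, the latter detected on 2 of the day 18.5 arrays (log2 change -2.63 to -1.29 over the alternatives). The homeobox gene Hoxa10 fell 2.84-fold (log2 change -1.86 to -0.83 over the alternatives). Hand2, a progesterone-induced stromal factor, was at least 1.72-fold higher (log2 change 0.69 to 2.28 over the alternatives). Of 23 progesterone-related genes, which include the study's own Zeb1 and Zeb2, 8 fell, 3 rose and 12 did not pass (9 and 4 adjusted over the list alone; median -0.14; adjusted p = 0.107). Oestrogen-responsive uterine genes lay higher at day 18.5: 10 of 19 rose, 4 fell and 5 did not pass, or 11 and 4 adjusted over the list alone (median 0.54, adjusted p = 0.0235, and adjusted p = 0.337 with an estimated correlation). Wnt7a, an epithelial Wnt ligand, was at least 5.67-fold higher (log2 change 2.00 to 4.83 over the alternatives). Wnt4 rose 3.17-fold, but the water channels Aqp8 and Aqp5 fell by 4.11 and 2.99. The adjusted p of this list was 0.0674 under a strict detection filter and 0.231 without the members it shares with other lists (0.00194 to 0.231 over the alternatives). In steroid and prostaglandin metabolism, Hsd17b2, which inactivates oestradiol and was detected on 1 array of day 15.5, rose by 3.06 on the log2 scale (1.89 to 3.79 over the alternatives), Ptges2 rose by 0.87, Star was at least 1.16-fold higher and the side-chain cleavage enzyme Cyp11a1 fell 3.08-fold. That list had 5 of 18 members higher, 2 lower and 11 not past the test, the same counts adjusted over the list alone, with a median of 0.03 and an adjusted p of 0.571.

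Published targets of the miR-200 family showed no common shift. Beside Zeb1 and Zeb2, which the study names and which are thus not independent evidence, Ntrk2 fell by 0.68 on the log2 scale, while Tcf7l1 and Rin2 rose by 0.69 and 0.68. Of 28 measured targets, 5 rose, 5 fell and 18 did not pass, with 6 higher and 5 lower adjusted over the list alone. The median was -0.02, the mean 0.02 and the adjusted p 0.998.

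Epithelial genes were higher and matrix genes lower at day 18.5. In the epithelium list, 15 of 23 members rose, 1 fell and 7 did not pass (19 and 1 adjusted over the list alone), with a median of 0.67 and an adjusted p of 2.01e-06, against an adjusted p = 0.384 with an estimated correlation. The tight junction gene Cldn4 rose 6.51-fold, the transcription factor Elf3 4.39-fold, the keratin Krt19 4.27-fold, the mucin Muc1 3.25-fold and Krt8, the brightest member, 2.17-fold; the protease inhibitor Spint1 fell by 0.71. Collagens and other structural matrix genes fell in 29 of 42 cases, rose in 4 and did not pass in 9, or 31 lower and 4 higher adjusted over the list alone (median -0.67, adjusted p = 4.60e-09, and adjusted p = 0.337 with an estimated correlation). Col1a1 fell 3.64-fold, the laminin Lamc1 2.94-fold and elastin, Eln, 2.41-fold. The 4 that rose were the matricellular genes Thbs1 (5.10-fold), Tnc (2.41-fold) and Thbs2 (1.98-fold), and fibronectin, Fn1 (1.33-fold). Matrix-degrading enzymes and inhibitors went both ways, with 6 of 27 higher, 7 lower and 14 not past the test (7 and 7 adjusted over the list alone). Stromelysins Mmp11, Mmp10 and Mmp3 rose 4.14-fold, 4.26-fold and 2.87-fold and Adamts4 rose 2.13-fold, while the list had a median of -0.17, a mean of 0.09 and an adjusted p of 0.571.

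Fibroblast and pericyte markers lay slightly lower: 7 of 17 fell, none rose and 10 did not pass, with 7 lower and 1 higher adjusted over the list alone (median -0.28, adjusted p = 0.0218, and adjusted p = 0.384 with an estimated correlation). Cspg4, Col14a1, Thy1 and Cd34 fell by 1.17, 0.84, 0.80 and 0.91 on the log2 scale, and Dcn, the brightest, changed by 0.01 (adjusted p = 0.964). The mean log2 signal of Dcn, 14.8 on both days, lay near the top of the arrays' range, where a saturated probe can hide a change. The call of the list ended with median scaling (0.0793), without replicate 3 of day 15.5 (0.0666) and without shared members (0.0576), over a range of 0.00278 to 0.0793.

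Transcripts of cytotoxic lymphocytes were much lower at day 18.5. Perforin, Prf1, fell 9.16-fold (log2 change -3.20 ± 0.17, SE), and the NK receptors Klrg1 and Klrd1 and the granule gene Nkg7 fell 8.36-fold, 6.09-fold and 4.18-fold, with Nkg7 detected on 2 of the day 18.5 arrays (log2 change -2.62 to -1.13 over the alternatives). Of 13 lymphocyte and NK genes measured, 6 fell and 7 did not pass (7 lower adjusted over the list alone; median -0.53; adjusted p = 1.13e-05, and adjusted p = 0.337 with an estimated correlation). Interferon-stimulated genes rose in 11 of 22 cases and fell in none, with 11 not past the test and 12 higher adjusted over the list alone (median 0.36). The antiviral genes Oasl2, Dhx58, Mx2 and Oasl1 rose by 0.97, 0.92, 0.95 and 1.29, and the list gave an adjusted p of 0.000904, or an adjusted p = 0.337 with an estimated correlation.

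Inflammatory cytokines and chemokines had 9 of 26 members higher, 4 lower and 13 not past the test, unchanged when adjusted over the list alone, with a median of 0.31 and an adjusted p of 0.177. The cytokines Il1a and Csf1 fell 6.40-fold and 6.54-fold, whereas the chemokines Ccl11 and Ccl4 rose 2.83-fold and 2.40-fold. Of 8 neutrophil genes, 4 rose and 4 did not pass, over the list alone as well (median 0.39, adjusted p = 0.0537). The risen members included Lcn2 (3.52-fold), the brightest, and Ltf (4.79-fold), both of which the uterine epithelium also makes under oestrogen, with Chil3 (log2 change 0.89) and S100a9 (0.67). At day 18.5 Lcn2 and Ltf had mean log2 signals of 15.00 and 15.07, near the top of the arrays' range. Their probes may be saturated there, so these folds may be too small. This list passed without replicate 1 or 3 of day 15.5 or replicate 2 of day 18.5 (adjusted p = 0.0479, 0.0167 and 0.0429; 0.0167 to 0.275 over the alternatives). The S100a9 call was lost without replicate 1 or 2 of either day (adjusted p = 0.0734 to 0.111; 0.00967 to 0.111 over the alternatives). Macrophage markers showed no common shift: 2 of 22 rose, 2 fell and 18 did not pass (4 and 4 over the list alone; 5 and 4 without background correction; median 0.11; adjusted p = 0.607). Cd14 rose 2.90-fold and Mrc1 and Ptprc fell by 0.71 and 0.87; Lyz1, the brightest, changed by 0.13 (adjusted p = 0.464), but rose by 0.66 with the mean of its probes (adjusted p = 0.0121) and by 0.91 with the gene names of the file (adjusted p = 0.00793; 0.00793 to 0.743 over the alternatives). H2-Aa rose by 1.49 (adjusted p = 0.0323), a call lost on leaving out any array but replicate 2 of day 15.5 (adjusted p = 0.0555 to 0.0901; 0.00433 to 0.108 over the alternatives).

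Transcripts of trophoblast, the fetal cell layer of the placenta, rose at day 18.5. Of 44 listed genes only 12 were measured; 10 of these rose and 2 did not pass, over the list alone as well. The list median was 3.43, from 2.07 without background correction to 4.67 with the authors' deposited values, or 2.74 with undetected members at their bound (adjusted p = 7.03e-09, and adjusted p = 0.337 with an estimated correlation). With all listed genes kept regardless of detection, the median was 0.08 and the adjusted p 0.000252. Beside the prolactin relatives and Ceacam11, the cathepsin Ctsj and the homeobox gene Rhox9 were at least 7.30-fold and at least 6.13-fold higher. On the day 18.5 arrays the risen members differed 3.15-fold, at the median, between the highest and the lowest array, against 1.21-fold for the other 1771 genes that rose. All 10 were highest on replicate 2 and lowest on replicate 3. Of the 15 epithelial genes that rose, 1 had the same order, against 15.8% of the risen genes outside the trophoblast list. So small a count does not set the epithelial genes apart from other risen genes. The 2 measured Y-linked genes, carried by male fetuses, did not pass the test. Ddx3y was at 8.29 ± 0.23 (SD, n = 3) and 8.01 ± 0.16 (adjusted p = 0.206) and Uty changed by -0.20 (adjusted p = 0.351). These 2 of 7 members were too few to test as a list, and the other members were detected on no array. They thus do not show whether the amount of fetal tissue differed.

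**Figure D2:**
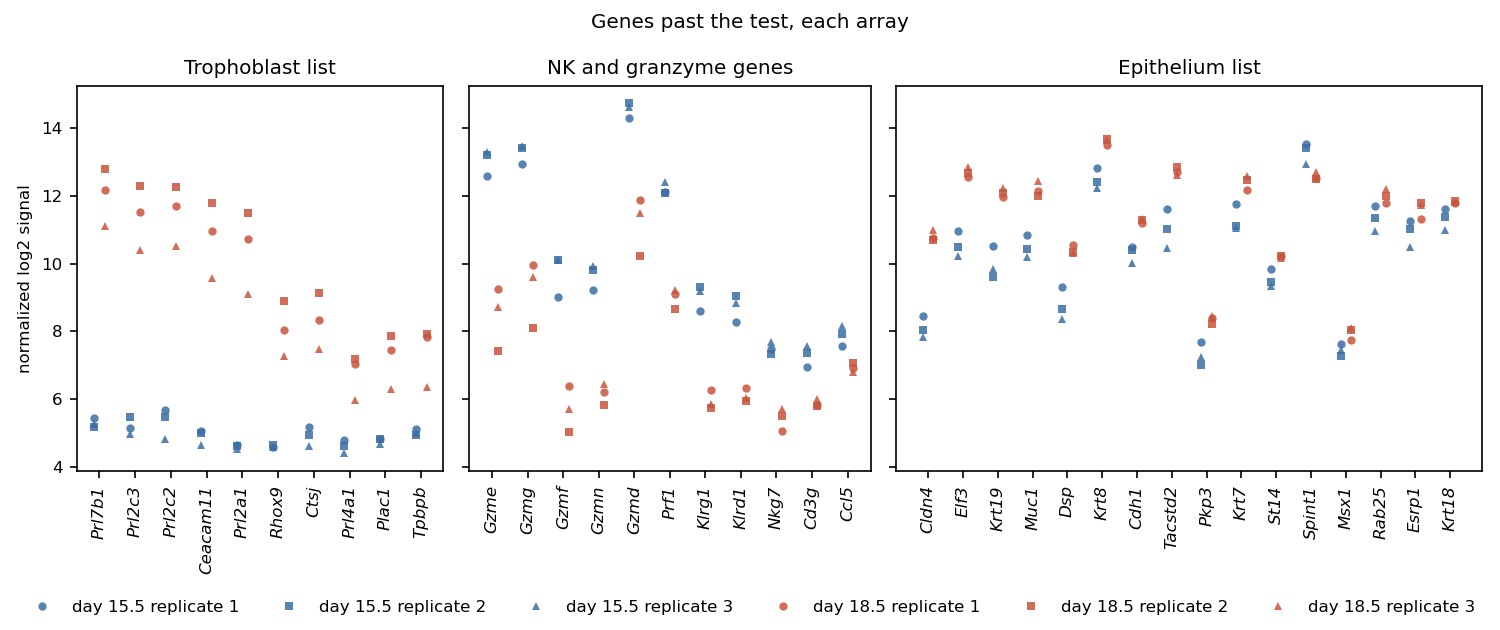
Normalized log2 signal of the genes past the test in the trophoblast list, among the NK and granzyme genes and in the epithelium list, with day 15.5 in blue, day 18.5 in red and a symbol for each replicate. Among the day 18.5 arrays, all 10 trophoblast genes are highest on replicate 2 and lowest on replicate 3. Of the 11 NK and granzyme genes, chosen by their fall, 9 are lowest on replicate 2. How often other fallen genes are lowest there was not counted, so no link between the 2 groups can be read from this.

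Genes of the decidua, the transformed uterine stroma, mostly fell without a shift of the list as a whole: 9 of 17 fell, 4 rose and 4 did not pass, the same over the list alone (median -0.62, adjusted p = 0.160). Bmp8a fell 2.59-fold, against the rises of Wnt4, Gja1 and Hand2, and the list passed without members shared with other lists (median -0.75, adjusted p = 0.00182; 0.00182 to 0.325 over the alternatives). Of 9 red cell genes, 4 fell, 1 rose and 4 did not pass, or 7 lower and 1 higher over the list alone and without background correction (median -0.76, adjusted p = 0.0214, and adjusted p = 0.337 with an estimated correlation). Hbb-y, an embryonic globin, was at least 6.10-fold lower and undetected at day 18.5 (log2 change -4.76 to -2.05 over the alternatives). Slc4a1 and Alas2 fell by 1.10 and 0.76. Hbb-b1, the brightest, changed by -0.30 (adjusted p = 0.0802) and passed in 5 alternatives. With the mean of its probes it changed by -0.48 (adjusted p = 0.00995, and 0.00995 to 0.997 over the alternatives). Its mean log2 signals of 14.98 and 14.68 lay near the top of the arrays' range, where a saturated probe can hide a change. The red cell call ended with median scaling (adjusted p = 0.0697; 0.00347 to 0.0697 over the alternatives). Endothelial genes had 5 of 18 lower, 1 higher and 12 not past the test (5 and 2 over the list alone; median -0.13; adjusted p = 0.108). The endothelial cadherin Cdh5 fell 3.24-fold, Plvap and Emcn fell by 0.74 and 0.57, Ramp2, the brightest, changed by -0.10, and Sox17 rose by 0.60 (adjusted p = 0.0330), a call lost on leaving out any array but replicate 3 of day 18.5 (adjusted p = 0.0509 to 0.112; 0.00437 to 0.112 over the alternatives). Without replicate 1 of day 15.5 the endothelial list passed (adjusted p = 0.0235; 0.0235 to 0.327 over the alternatives).

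Skeletal muscle genes lay lower at day 18.5, with 5 of 9 lower, 1 higher and 3 not past the test (6 and 1 over the list alone). Acta1, skeletal actin, which smooth muscle also expresses, fell 6.09-fold and the troponin Tnni2 2.96-fold, Tnnc2 was at least 1.42-fold lower, and Ttn fell by 1.12, a call lost for the mean of its probes (log2 change -0.47, adjusted p = 0.0508; 9.29e-05 to 0.0508 over the alternatives). The list median was -1.02, or -0.51 without background correction and -0.90 with bounds (adjusted p = 0.0162, and adjusted p = 0.337 with an estimated correlation). Adipose and mesothelial markers, which also hold keratins of stratified epithelium, had 3 of 8 higher and 5 not past the test (4 higher over the list alone; median 0.46; adjusted p = 0.208). The keratins Krt14 and Krt5 rose by 3.06 and 1.25 on the log2 scale, with Krt5 detected on 2 of the day 15.5 arrays (0.67 to 1.59 over the alternatives), and Upk1b rose by 0.90 (adjusted p = 0.0269), the last lost without replicate 1 or 2 of day 15.5 or replicate 2 or 3 of day 18.5 (adjusted p = 0.0501 to 0.0905; 0.00308 to 0.0905 over the alternatives).

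Genes of the unfolded protein response were lower as a list, while a few members rose. Of 27, 10 fell, 3 rose and 14 did not pass, with 14 lower and 3 higher over the list alone (median -0.34, adjusted p = 0.0189, and adjusted p = 0.337 with an estimated correlation). The endoplasmic reticulum gene Creld2 fell by 0.90, and the ATF4 targets Trib3 and Chac1 rose by 1.05 and 1.19. The call ended with median scaling (adjusted p = 0.116; 0.00136 to 0.116 over the alternatives). No single ribosomal protein gene of 41 passed the test, over the list alone either, though 12 passed with median scaling and 4 without background correction. The list lay slightly higher (median 0.15, or 0.40 with median scaling; adjusted p = 0.0360, and adjusted p = 0.665 with an estimated correlation). That call was lost without replicate 2 or 3 of day 15.5 or replicate 1 or 2 of day 18.5 (adjusted p = 0.0874, 0.0939, 0.0714 and 0.0968; 3.45e-06 to 0.0968 over the alternatives). Oxidative phosphorylation had 1 of 52 genes higher, Cox7b, by 0.58 (adjusted p = 0.0343), and 51 not past the test, with none adjusted over the list alone, against 7 higher with median scaling and 6 without background correction. The Cox7b call was lost without replicate 1 or 2 of either day (adjusted p = 0.0585 to 0.118; 0.0183 to 0.118 over the alternatives). The list gave a median of 0.10 and an adjusted p of 0.116, but 0.00269 with median scaling and 0.0437 without replicate 1 of day 15.5 (0.00269 to 0.309 over the alternatives).

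Cell cycle genes stayed mostly below the threshold, with 4 of 40 higher, 4 lower and 32 not past the test, the same over the list alone (median -0.01, adjusted p = 0.709). Rrm2, a subunit of ribonucleotide reductase, fell 10.1-fold, the cyclins Ccnd1 and Ccne2 fell by 0.91 and 0.77, and Mcm7 rose by 0.58. Ccne2 was detected on 2 of the day 18.5 arrays (log2 change -1.07 to -0.35 over the alternatives). In hypoxia and glycolysis, Ddit4, a stress-induced inhibitor of mTOR, rose 5.12-fold, and Higd1a (detected on 1 array of day 18.5; -1.90 to -0.71 over the alternatives), P4ha2 and Vegfa fell by 1.43, 1.11 and 0.98; 3 of 31 rose, 6 fell and 22 did not pass, the same over the list alone (median -0.03, adjusted p = 0.418). Cholesterol biosynthesis had 2 of 21 higher, 5 lower and 14 not past the test (2 and 6 over the list alone; median -0.06; adjusted p = 0.607), with Hsd17b7, an enzyme of the pathway, rising by 0.70 and Fdps, which makes farnesyl diphosphate, falling by 0.47. Of 23 immediate early genes, 3 rose, 4 fell and 16 did not pass, the same over the list alone (median 0.05, adjusted p = 0.961). Without background correction 5 rose and 4 fell, and with median scaling 5 rose and 3 fell. Gadd45g and Gadd45b rose by 0.92 and 0.80, and Klf2 and Egr2 fell by 0.95 and 1.12.

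**Figure D3:**
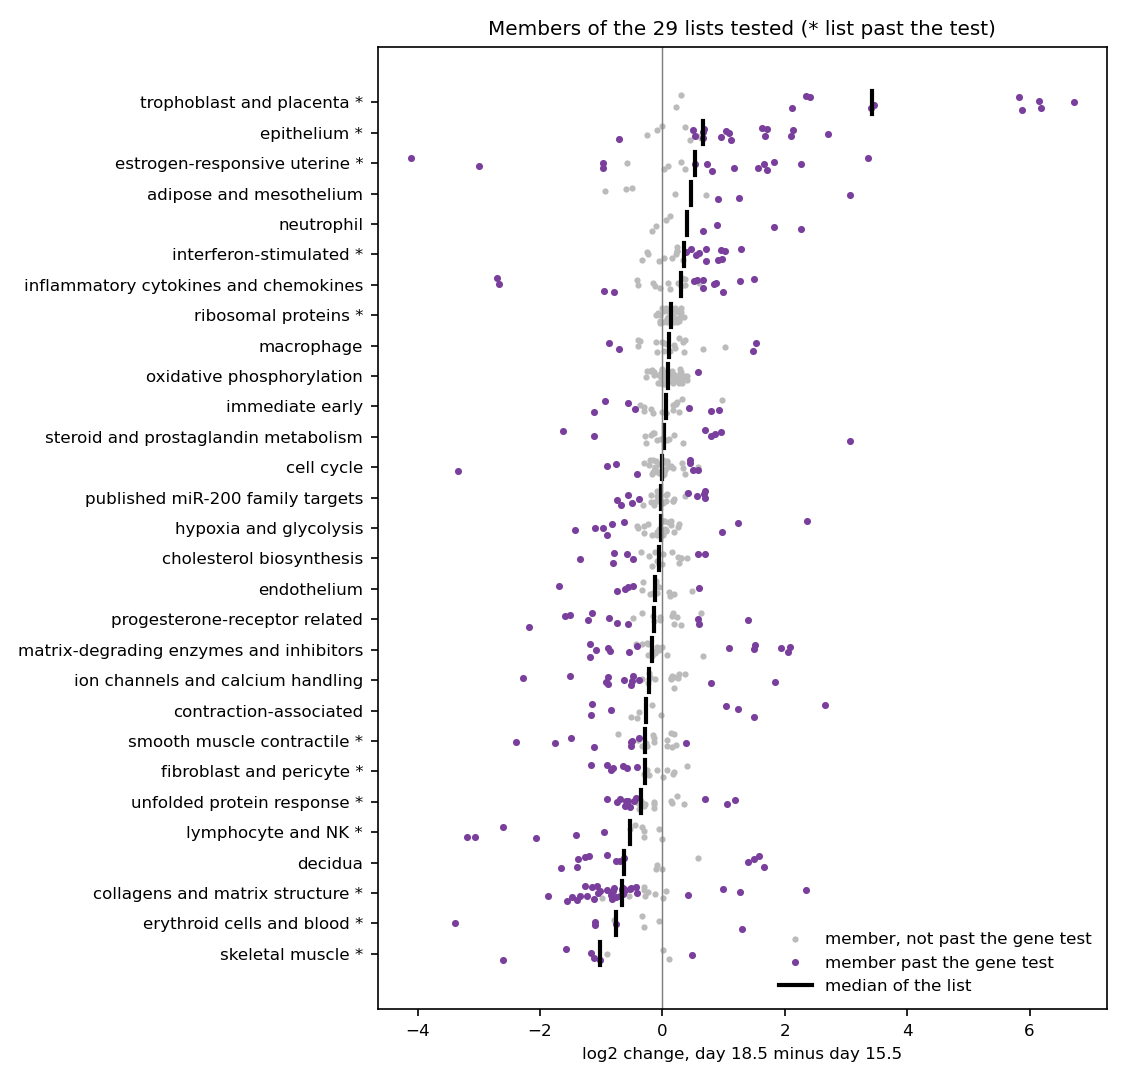
Log2 change from day 15.5 to day 18.5 of each measured member of the 29 lists tested (points, purple where the member passed the gene test), with the list median as a bar and an asterisk where the list passed. Medians run from 3.43 for trophoblast to -1.02 for skeletal muscle genes, and 12 lists passed with the preset correlation, none with an estimated one.

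The authors' deposited table of the same comparison lists 2047 probes with a ratio above 1 and 2499 below 1 at a false discovery rate under 0.05. Among 20257 probes with a rate in the authors' deposited table that were also tested here, 3897 were called by both, all in the same direction, 1231 only here and 6 only in that table.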

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

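The fit with file gene names and the lists without shared members were chosen after the data were seen; the other alternatives were planned. No alternative turned the direction of a named gene called in the first fit; Acta2, not called there, was lower with the mean of its probes (-0.40, adjusted p = 0.0214). Over refits of all genes, 2710 (without day 18.5 replicate 2) to 4265 (array weights) genes were called. Leaving out each array gave 2710 to 3418 changed genes, 1287 to 1687 higher and 1423 to 1731 lower, and 11 to 15 lists past the test. An unmoderated statistic called 2352 genes (1187 higher, 1165 lower). It lacks the 4.93 prior degrees of freedom of the moderated fit, and whether that alone lowers the count was not tested. A minimum of 2-fold left 1090 (555 and 535) by its construction. Of 124 named genes called, 116 were called in every setting in which they were refitted. Those settings leave out the unmoderated statistic, the 2-fold minimum and single probes. With an estimated correlation 0 lists passed, and fry, which does not compare a list with other genes, called 19, against 12 with the preset correlation; other settings gave 9 to 15. Lists past the test only under fry were contraction-associated genes (adjusted p = 0.0176), ion channels (0.00298), progesterone-related genes (0.00298) and steroid metabolism (0.0273). Without a detection filter cytokines (0.0316; 0.0316 to 0.404 over the alternatives), endothelium (0.0391) and oxidative phosphorylation (0.0282) passed, and neutrophil genes passed with the mean of probes (0.0346); fry also called the cytokine, neutrophil and decidual lists. With 3 arrays per day, changes of 0.5 on the log2 scale were mostly not recovered in simulation. The adjusted threshold there was stricter than in the data, so that rate does not describe the data. Among measured genes, changes near that size passed in some cases and not in others. In limma, Ccl9 (0.45, adjusted p = 0.0275) passed and Ccl25 (0.50, adjusted p = 0.0930) did not.

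Equal replicate numbers across days did not pair the arrays: deviations from the day means correlated at -0.164, 0.146 and -0.0626 for replicates 1, 2 and 3, and 2 of 6 arrays correlated best with their own number. With the number as a block, 3217 genes were called (1550 higher, 1667 lower), 3099 of them shared with the fit without the block.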

Other observations

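All tests in this part except the count over splits were chosen after the results were seen, and what would decide those on placental tissue, yolk sac, a single source, NK genes and the share of epithelium was revised after first values. Gene families told by the start of their symbols added to the picture, with 350 families and 700 directions tested against the share of all genes called. Keratins rose in 15 of 22 cases, where 2.78 were expected (1-sided Fisher's exact test, adjusted p = 1.06e-06, median log2 change 1.18). This test takes the genes of a family as independent. The risen keratins included Krt6b, Krt20 and Krt84, which rose by 3.28, 3.14 and 3.22, and Krt14. Krt6b was detected on 1 array of day 15.5, so its change hangs on the background. Krt23, Krt80 and Krt90 fell. Kallikreins, serine proteases of glands, fell in 10 of 14 cases, where 1.88 were expected, and rose in none (adjusted p = 0.000256, median -0.75). Klk15 fell by 2.22 and Klk4 by 1.57 on the log2 scale, and with median scaling 9 kallikreins fell. The Klk1b genes are near-identical copies that probes may not separate, so the test may count 1 transcript several times. Chemokines of the Ccl family rose in 8 of 15 cases, where 1.9 were expected, and fell in 2 (adjusted p = 0.0236, median 0.50). With the authors' deposited values 6 rose and 1 fell. The risen members included the lymphoid chemokines Ccl21a and Ccl21c, near-identical copies that probes may not separate. The Ccl21a probe was originally labelled Ccl21b. Solute carriers fell in 50 of 226 cases, where 30.3 were expected, and rose in 27 (adjusted p = 0.0236, median -0.14). Collagens fell in 19 of 33, where 4.42 were expected (adjusted p = 1.06e-06). Prolactin relatives rose in 8 of 10, where 1.26 were expected (adjusted p = 0.000401), but the Prl2c copies among them may likewise be counted several times. Most of the 8, such as Prl7b1 and Prl2a1, passed the detection filter through day 18.5 alone. Relatives such as Prl3d1 and Prl5a1, detected on no array, were left out. The count is thus tilted towards rises and does not describe the whole family. The prolactin relative that fell was Prl8a2, a product of decidua, from 11.87 ± 0.40 (SD, n = 3) to 10.21 ± 0.37. Family medians kept their sign under each scaling.

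Trophoblast transcripts were strong on the day 18.5 arrays only. Placental tissue as a whole stays open: 12 late-placental transcripts of that list had a median log2 change of 0.0577 (SD 0.122), but none of them is among the 10 genes that rose and 8 were detected on no day 18.5 array, so they exclude nothing. Yolk sac tissue stays open too: 12 measured yolk sac genes had a median change of -0.113 (SD 1.93), with 3 of them (25%) higher and 3 lower (Amn, Rbp4 and Dab2). Of the 12, 7 shared an order of the day 18.5 arrays, among them the risen Apoa1, Afp and Fgg and the fallen Amn. Replicate 3 was highest, then 2, then 1, an order found in 21.5% of the other genes tested. None of the 10 risen trophoblast genes had that order; 100% of them had replicate 2 highest, then 1, then 3, against 15.8% of the other risen genes. Both orders were read from the genes they describe, so they do not test a source, but tissue of the conceptus sampled unevenly may explain both, and whether it came with dissection or belongs to the uterus at day 18.5 was not tested.

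NK transcripts were weighed over all 18 measured genes, the lymphocyte and NK list with 5 granzymes added after their falls were seen (median log2 change -1.74), since the 11 that fell (median -3.20) are chosen by their fall. These granzymes are close relatives whose probes may read each other's transcripts, and without them the list median was -0.53. Less decidua in the later samples, where uterine NK cells lie, stays open: the largest fall in that list, -1.66 ± 0.24 (SE) for Prl8a2, comes near the median of the 18 genes, while the decidual median was -0.62. A smaller share of all leukocytes would lower macrophage genes too, but their median change was 0.106 (SD 0.605), above that of the 18 genes by 1.84 and above that of the list without granzymes, -0.53, by 0.64. That list mixes 2 called rises and 2 called falls among 22 genes. Ptprc, a gene of leukocytes in general, was 1 of the falls (-0.87, limma, adjusted p = 0.0022), so a partial loss of other leukocytes stays open. The choice of all measured genes was made after a first result on those that fell. Fewer NK cells, fewer granule transcripts in each or less decidua may underlie the falls.

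Epithelial genes rose at day 18.5 while Zeb1 and Zeb2 fell. A larger share of epithelium stays open: the log2 changes of its genes spread with an SD 4.44 times their median SE, but the 17 lists not past the test had 1.45 to 8.40, so this decides nothing. Were loss of repression by ZEB1 and ZEB2 the cause, published ZEB-repressed genes could be expected to rise more; the 9 measured had a median of 0.66 against 1.11 for the other 14, a difference of -0.45 (two-sided permutation test, p = 0.181), which leaves the question open, as does a response of the epithelium to hormones, untested here.

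Splitting the 6 arrays in other ways gives 10 splits, of which 1, the real split, gave as many changed genes (3669; the highest other split gave 0). With so few splits the share cannot go under 0.1.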
